A study of Homo sapiens with 12 samples.

How the data were processed

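RNA was measured in 12 libraries of the A549 lung carcinoma line, with 3 biological replicates in each of 4 groups: DMSO control and 10 µM SAHA, each at 24 h and 48 h. Per the labels' protocols, cells were treated as confluent monolayers, treated and control flasks of a replicate were handled together, and RNA was treated with DNase and depleted of ribosomal RNA before library preparation. Replicates are called biological in the labels and were separate flasks of 1 line.

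The deposited values are a signal, gene read counts divided by a size factor per library, for 47952 genes, per the labels, which describe DESeq2 result tables with normalised values. Beside them the authors deposited log2 fold changes with standard errors from DESeq2, per the file headers. The authors also deposited the adjusted p-value of DESeq2 for each gene and time, per the file headers. The submitters' processing notes name FastQC, STAR, HTSeq, DESeq2 and DESeq among tools for several assays, with the T2T-CHM13 build, and give no versions. The role of each tool and the strand setting of the counting were not given in the sources used here, so antisense and overlapping genes are uncertain, as are near-identical copies. Of the gene symbols, 43861 of 47952 (91.5%) are RefSeq symbols or synonyms of the reference used here, GRCh38, from which no coordinates are printed.

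Both tables held the same 12 columns of values, with a largest difference of 0. The design had assumed separate normalisation for each time and was kept: each time was tested on its own 6 libraries, and the difference between times on all 12. Every normalised value was a whole multiple of a fixed step in its library (100% of values, tolerance 0.001 reads), so whole reads were recovered. They came to 7321966 to 10838710 reads per library. A gene without a read in a library is limited to 3 reads there, which is at most 3.64 normalised reads. Such limits and counting intervals cover counting error only.

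The main test was limma (3.58.1, in R 4.3.3), two-sided, on log2(value + 1) with moderated variances and a mean-variance trend, for genes at 10 or more in at least 3 of the 6 libraries. Benjamini-Hochberg adjusted p under 0.05 was called. Gene lists (39, fixed before the data were examined) were tested by limma's camera with a preset inter-gene correlation of 0.01 where at least 5 members were tested, which left 34 lists at 24 h and 32 at 48 h. Beside it stand camera with an estimated correlation and fry, a rotation test of whether a list's genes move one way on balance. The count of called members was taken over all genes and adjusted over the list alone. The 13 mitochondrially encoded genes of another list are not among the values used here. Setting members without a read in a group to their limit left every list median as it was.

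Genes were named by a rule fixed beforehand: per time, the 8 largest rises and 8 largest falls among called genes whose replicates did not overlap and whose higher group mean was at least 100, passing over unnamed loci, Y-linked genes and XIST. The rule adds the member with the largest rise and largest fall at 24 h of each list described, any member of a list of 11 or fewer, fixed genes (among them CDKN1A, HDAC1, HDAC2, HDAC3, HDAC6, MYC, CCND1, MKI67 and TYMS) and the 5 largest positive and 5 largest negative differences between times. Some genes that the rule names are not reported here. MALAT1 and NEAT1 lie outside this rule and were chosen after their values were seen.

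Per the labels' protocols the treated and control flasks of a replicate were harvested together and thawed as a pair, so replicate numbers pair the libraries. Correlations of their deviations from the group means were 0.222, 0.0396 and 0.173 for the 3 pairs at 24 h and 0.047, 0.0127 and 0.00256 at 48 h. A fit with replicate as a block was an alternative, given beside a result where it changed the call. Further alternatives were pseudocounts of 0.5 and 5, no filter and a minimum of 50, TMM (edgeR 4.0.16) and equal-total scaling, no variance trend, leaving out each library, edgeR's quasi-likelihood test and DESeq2 (1.42.0) on the recovered reads, and the authors' table. On the recovered reads edgeR called 11314 genes at 24 h, 9080 at 48 h and 7264 differences, and DESeq2 10358, 7882 and 6601.

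The pipeline was tested on simulated data with 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold, all above a minimum control level. Genes were simulated as independent, with a spread set by their level. In the data 70.8% of tested genes were called at 24 h, so the rates below need not hold there. Of the 1.5-fold, 2-fold and 4-fold changes it recovered 71.6%, 94.0% and 100% at 24 h among 14495 genes, with 6.84% of calls false. At 48 h it recovered 82.1%, 94.0% and 100% among 14467 genes with 4.66% false, and for the difference 52.2%, 91.0% and 100% among 14793 genes with 4.14% false. With no change simulated it made no call.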

Results

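Gene expression was measured by sequencing of ribosomal RNA-depleted total RNA in A549 cells, an established lung carcinoma line. Confluent cultures received 10 µM SAHA (suberoylanilide hydroxamic acid, or vorinostat), an inhibitor of the zinc-dependent histone deacetylases (HDACs), or its solvent DMSO as control. Cells were collected after 24 h and after 48 h, with 3 biological replicates in each of the 4 groups and 12 libraries in all. The recovered reads assigned to genes ranged per library from 9740021 to 10838710 in controls and from 8302787 to 9726063 with SAHA at 24 h. At 48 h they ranged from 9214441 to 10121492 in controls and from 7321966 to 9631172 with SAHA. Libraries treated with SAHA for 24 h had reads in 25497 ± 211 genes (mean ± SD, n = 3), and their controls in 22505 ± 279. At 48 h these numbers were 23963 ± 261 with SAHA and 22202 ± 102 in controls. On the first principal component, which held 69.0% of the variance, the 3 libraries with 24 h of SAHA lay between 99 and 103.5, those with 48 h between 32.63 and 41.38, and the 6 controls between -72.32 and -67.8. Levels below are normalised reads, given as mean ± SD over 3 libraries, and log2 changes are SAHA minus control on the scale of log2(value + 1), which understates the change of low genes.

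The 24 h comparison asked which transcripts changed during the first day of HDAC inhibition. Genes that were almost silent in control cells reached high levels with SAHA. DHRS2, a short-chain dehydrogenase/reductase, rose from 16.9 ± 4.76 to 6231 ± 509.7 (368-fold), and ATP1B2, a beta subunit of the sodium and potassium pump, rose from 1.68 ± 1.45 to 1401 ± 67.9 (834-fold). Genes of dividing cells fell together: all 34 tested G2/M and mitosis genes, all 17 genes of homologous recombination and Fanconi repair and 35 of 36 genes of DNA replication and nucleotide supply were lower. Thymidylate synthase (TYMS), which makes the thymidine nucleotide for DNA synthesis, fell from 806 ± 29.3 to 60.8 ± 5.69, and the proliferation marker MKI67 fell from 7284 ± 234 to 2689 ± 166.

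The other largest rises at 24 h were in a membrane receptor, carcinoembryonic antigen family members, a ciliary motor and a cyclin. GPR50, an orphan G protein-coupled receptor, had no read in the 3 controls and reached 576 ± 23.3. That was at least 661-fold higher against a floor of 3 reads over the group. Likewise CEACAM20 reached 238 ± 29.4 (at least 275-fold higher) and CCND2, which encodes cyclin D2, reached 181 ± 25.7 (at least 209.6-fold higher). The pseudogene CEACAM22P rose from 1.45 ± 1.77 to 648 ± 72.3. It belongs to the same family as CEACAM20, and reads of such relatives are hard to assign, so both levels are uncertain. NGFR, a receptor for nerve growth factor, rose 692-fold (95% counting interval 201 to 6010.3) and DNAH12, a heavy chain of ciliary dynein, rose 517-fold (95% counting interval 147 to 4407). Among the largest falls were BAAT, which conjugates bile acids (from 254 ± 15.2 to 10.5 ± 6.66), and SPDEF, a transcription factor of secretory epithelium (from 313 ± 25.02 to 16.1 ± 2.31). Others were VSIG1, an immunoglobulin-domain adhesion protein (from 159.6 ± 29.5 to 7.27 ± 3.88), and CACNG6, a calcium channel gamma subunit (from 445 ± 34.6 to 21.9 ± 9.68). The histone variant gene MACROH2A2 fell from 194 ± 3.59 to 12.4 ± 4.42, and GALNTL6, which resembles glycosyltransferases, from 128.1 ± 15.99 to 7.41 ± 2.91. The histone H2A gene H2AC21 fell from 664 ± 30.5 to 40.9 ± 6.03, which is uncertain, since histone genes have near-identical copies. The 8 rises had adjusted p of at most 7.36e-09 and the falls named of at most 3.54e-07 (limma with Benjamini-Hochberg adjustment).

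The gene lists were fixed before the data were examined, as were the tests and the rule for naming genes. Of the 36 tested genes of DNA replication, 0 were higher and 35 lower at 24 h (median log2 change -2.15, camera adjusted p = 2.1e-15, adjusted p = 0.125 with an estimated correlation). Mitosis genes had a median of -1.50 (camera adjusted p = 2.1e-15, adjusted p = 0.201 with an estimated correlation). Homologous recombination and Fanconi genes had a median of -1.92 (camera adjusted p = 1.27e-08, adjusted p = 0.125 with an estimated correlation). All 18 tested replication-dependent core histone genes were lower (median -2.33, camera adjusted p = 3.45e-09, adjusted p = 0.125 with an estimated correlation). One of them, H2AC4, fell from 241 ± 15.4 to 21.2 ± 5.73, and reads of these near-identical copies are hard to assign. Of 14 G1 cyclins, their kinases and E2F/RB factors, 9 fell and 2 rose. E2F1 was among those that fell (from 274 ± 14.6 to 33.2 ± 8.38). The G1 list's median was -0.90 (camera adjusted p = 0.0404, adjusted p = 0.226 with an estimated correlation). Counts adjusted over the list alone were the same for these 5 lists at 24 h.

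Genes that shape chromosomes were also lower at 24 h. Among 13 condensin and lamin genes 11 fell, including the lamina protein LMNB1 (from 1110.1 ± 47.7 to 181 ± 3.68), and 1 rose. The list stood below other genes (median -1.22, camera adjusted p = 0.000213, adjusted p = 0.161 with an estimated correlation). CTCF, cohesin and cohesin regulators fell in 10 of 13 genes (median -0.61, camera adjusted p = 0.00199, adjusted p = 0.444 with an estimated correlation). Among them ESCO2, a cohesin acetyltransferase, fell from 673 ± 17.9 to 241 ± 17.99. Histone acetyltransferases and bromodomain readers fell in 12 of 15 genes and rose in 2 (median -0.64, camera adjusted p = 0.0112, adjusted p = 0.226 with an estimated correlation). Ribosome biogenesis genes fell in 22 of 23 (median -0.69, camera adjusted p = 1.29e-06, adjusted p = 0.225 with an estimated correlation). UTP20, which acts in ribosomal RNA processing, fell from 1239.96 ± 41.8 to 256 ± 18.5.

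A549 cells have constitutively active NRF2, the regulator of antioxidant genes. At 24 h 16 of 23 NRF2 target genes fell and 6 rose (median -0.68, camera adjusted p = 0.00318, adjusted p = 0.531 with an estimated correlation). The aldehyde dehydrogenase ALDH3A1 fell from 12484 ± 314 to 914 ± 155, whereas SRXN1, which repairs oxidised peroxiredoxins, rose from 3335 ± 36.1 to 7497 ± 865. Targets of ATF4 and the unfolded protein response fell in 11 of 18 genes and rose in 2. The transcription factor XBP1 fell from 1500.1 ± 89.3 to 278 ± 49.2. The ATF4 list stood below other genes (median -0.59, camera adjusted p = 0.00502, adjusted p = 0.444 with an estimated correlation). Neuronal and REST-repressed genes rose in 22 of 26 and fell in 2 (23 and 2 adjusted over the list alone), with a median of 2.68 (camera adjusted p = 1.31e-06, adjusted p = 0.125 with an estimated correlation). The filter on low values admits members silent in controls only if they rose, which raises this share and median. Among the 17 members with a control mean of at least 10 at the other time, 13 rose and 2 fell (median 1.35, camera adjusted p = 6.34e-05, an alternative chosen after seeing the data). SYN1, a synaptic vesicle protein, went from 1 read over the 3 controls to 142 ± 33.5, while CPLX2, another presynaptic protein, fell from 13995 ± 303 to 1308 ± 265. Genes that other studies report as responding to HDAC inhibitors rose in 8 of 11 and fell in 3 (camera adjusted p = 0.0418, adjusted p = 0.444 with an estimated correlation). They include TXNIP, an inhibitor of thioredoxin (from 153 ± 18.5 to 3344 ± 381) and the cell cycle inhibitor CDKN1A (from 482 ± 59.5 to 1197 ± 199.5). The falling members were TYMS, the cyclin CCND1 (from 2904 ± 46.1 to 1055 ± 72.7) and CTPS1, which makes cytidine nucleotides (from 809 ± 23.9 to 533 ± 13.96). Adjusted over the list alone, counts for the NRF2, ATF4, HDAC-inhibitor, chromosome and ribosome lists were the same at 24 h.

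Of the 11 zinc-dependent deacetylases, the family that holds the drug's targets, 3 rose and 3 fell at 24 h (camera adjusted p = 0.835). HDAC3 rose from 315 ± 39.9 to 566 ± 43.97 at 24 h (log2 change 0.85, limma with Benjamini-Hochberg adjusted p = 1.33e-05) and HDAC5 from 235 ± 45.1 to 646 ± 90.1 (log2 change 1.46, adjusted p = 1.13e-06). HDAC9 rose from 43.2 ± 6.58 to 77.5 ± 16.5 (limma adjusted p = 0.00354). HDAC7 fell from 491 ± 58.8 to 206 ± 15.1 (log2 change -1.25, limma adjusted p = 4.85e-07) and HDAC4 from 493 ± 8.65 to 339 ± 10.3 (log2 change -0.54, adjusted p = 3.78e-05). HDAC8 fell from 234 ± 15.2 to 188 ± 14.3 (limma adjusted p = 0.0164, 0.0771 and 0.0555 without control replicate 3 or SAHA replicate 1, and 0.0529 in DESeq2). HDAC1 did not pass the test (802 ± 27.6 in controls and 843 ± 15.7 with SAHA, limma adjusted p = 0.323), nor did HDAC2 (1001 ± 60.3 and 980.2 ± 11.3, adjusted p = 0.712). HDAC6 was at 565 ± 29.8 in controls and 506 ± 21.4 with SAHA (limma adjusted p = 0.0772, 0.0435 with replicate as a block, 0.0194 with TMM scaling and 0.0258 with equal totals). The growth regulator MYC fell from 2809.6 ± 479.7 to 1939.7 ± 306 (log2 change -0.53, limma adjusted p = 0.00189). Death regulators moved in both directions: BMF, a pro-apoptotic BCL2 family member, rose from 38.3 ± 1.76 to 301 ± 14.4, and BID, of the same family, fell from 214 ± 6.90 to 39.6 ± 2.12. BIRC3, an inhibitor of apoptosis, rose from 589 ± 25.6 to 4135 ± 233. Their lists did not pass (camera adjusted p = 0.709 for pro-apoptotic genes and 0.835 for anti-apoptotic genes). The p53 target list did not pass either, with 8 of 25 higher and 8 lower, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.832).

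Over all genes, limma called 11233 of 15876 tested genes at 24 h at a Benjamini-Hochberg adjusted p under 0.05, with 5658 higher and 5575 lower. The balance of directions depended on the scaling, with 5215 higher and 6075 lower by TMM and 5329 and 5959 with equal totals. Of these, 4798 changed at least 2-fold, 2841 upward and 1957 downward. The count of genes at least 2-fold higher was 1675 to 1685 when any 1 SAHA library was left out, since genes silent in controls then could not pass the filter on low values, and 2831 to 2877 when the tested genes were those of all 6 libraries, an alternative chosen after seeing the data. No list kept its call with an estimated correlation between genes. That held also for the neuronal (0.00298) and G1 (-0.00808) lists, whose estimates lay below the preset 0.01, although most estimates were higher. A call lost in that version of the test thus need not come from correlated members. The count of at least 2-fold changes was 7767 without the filter and 2966 with a minimum of 50.

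**Figure D1:**
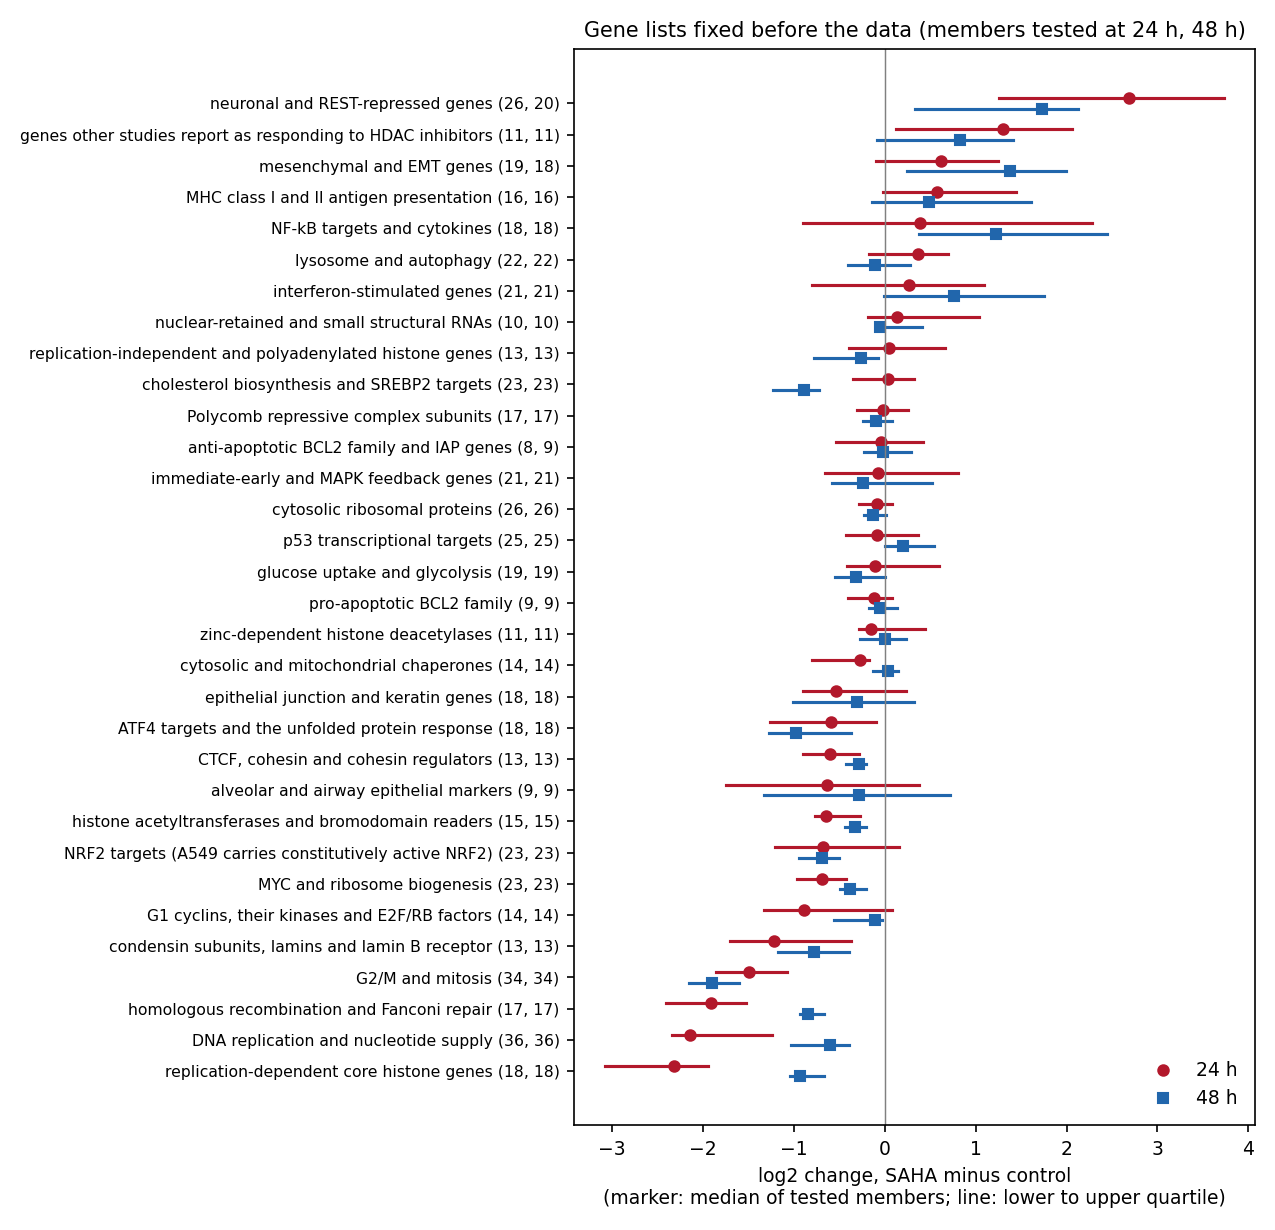
Median log2 change (SAHA minus control, horizontal axis) of the tested members of each gene list, with circles for 24 h, squares for 48 h and lines from the lower to the upper quartile of the members. The replication-dependent core histone list lies lowest at 24 h, at a median of -2.33, and the neuronal and REST-repressed list highest, at 2.68, a value raised by the filter on low values.

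The 48 h comparison asked the same question after a further day of exposure. Mitosis genes were lower throughout, with all 34 of 34 falling and MKI67 going from 2683 ± 145 to 719.96 ± 115.8. Cholesterol biosynthesis genes fell in 21 of 23. NF-kB targets and cytokines rose in 16 of 18 genes and fell in 1, and the cytokine IL1A rose 22.4-fold (95% counting interval 6.85 to 105). CCN2, a matricellular growth factor among the mesenchymal genes, rose from 1233 ± 117.7 to 5055 ± 167.

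Among the largest rises at 48 h was again CCND2, at no read in controls and 117.05 ± 12.6 with SAHA (at least 121.6-fold higher). Then LAMA1, a laminin chain of basement membranes, rose 199-fold (95% counting interval 54.9 to 1655), and CADM3, a cell adhesion molecule, 321-fold (95% counting interval 57.2 to 12727). NCAM1, the neural cell adhesion molecule, rose 46.5-fold, and NRXN2, a presynaptic adhesion protein, 48.3-fold. The carboxypeptidase CPA4 rose from 2.19 ± 1.04 to 111 ± 24.5, the membrane protein TMEM255A from 1.31 ± 1.13 to 153 ± 25.2 and ATP1B2 from 3.22 ± 2.56 to 125.6 ± 18.6. Among the largest falls, MYO7B, a brush border myosin, fell from 171 ± 24.8 to 1.73 ± 0.910, and the vitamin C transporter SLC23A1 from 366 ± 21.2 to 17.9 ± 7.02. Falls were also seen in the plasma retinol carrier RBP4 (from 399 ± 39.8 to 28.02 ± 10.4) and the secreted protease HABP2 (from 149 ± 21.7 to 5.00 ± 4.66). The alcohol dehydrogenase ADH6 fell from 192 ± 15.3 to 10.4 ± 2.74 and EPS8L3, related to the EPS8 signalling adaptor, from 267 ± 28.3 to 17.5 ± 4.86. SPDEF (from 392 ± 53.8 to 27.9 ± 4.44) and VSIG1 (from 163 ± 29.8 to 9.03 ± 1.61) were again among the 8 largest falls. The 8 rises had adjusted p of at most 1.06e-11 and the 8 falls of at most 7.23e-11 (limma with Benjamini-Hochberg adjustment).

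At 48 h the mitosis list had a median log2 change of -1.90 (camera adjusted p = 2.65e-24, adjusted p = 0.132 with an estimated correlation). DNA replication genes fell in 29 of 36 and rose in 2, with 30 and 2 adjusted over the list alone (median -0.60, camera adjusted p = 6.73e-07, adjusted p = 0.122 with an estimated correlation). TYMS fell from 341 ± 26.8 to 165 ± 9.79. Homologous recombination and Fanconi genes fell in 16 of 17 (median -0.84, camera adjusted p = 1.25e-05, adjusted p = 0.122 with an estimated correlation). Core histone genes fell in 16 of 18 (median -0.93, camera adjusted p = 1.77e-05, adjusted p = 0.229 with an estimated correlation). Condensin and lamin genes fell in 12 of 13 (median -0.78, camera adjusted p = 3.56e-06, adjusted p = 0.122 with an estimated correlation). Cohesin and CTCF genes fell in 11 of 13 (12 adjusted over the list alone, median -0.29, camera adjusted p = 0.00174, adjusted p = 0.122 with an estimated correlation). Acetyltransferases and bromodomain readers fell in 11 of 15 (median -0.33, camera adjusted p = 0.00146, adjusted p = 0.122 with an estimated correlation). Ribosome biogenesis genes fell in 16 of 23 (17 adjusted over the list alone, median -0.38, camera adjusted p = 0.000105, adjusted p = 0.207 with an estimated correlation). Replication-independent and polyadenylated histone genes had 7 lower and 2 higher of 13, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0504, and 0.0446 with replicate as a block, adjusted p = 0.466 with an estimated correlation).

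The cholesterol, NRF2 and ATF4 lists fell at 48 h. The cholesterol list had a median of -0.89 (camera adjusted p = 3.24e-10, adjusted p = 0.122 with an estimated correlation). NRF2 targets fell in 21 of 23 (median -0.69, camera adjusted p = 9.47e-11, adjusted p = 0.122 with an estimated correlation), and ALDH3A1 fell from 9939 ± 186 to 3443 ± 469.99. ATF4 and unfolded protein response genes fell in 14 of 18 and rose in 1 (median -0.98, camera adjusted p = 3.35e-06, adjusted p = 0.122 with an estimated correlation), and XBP1 fell from 2172 ± 107 to 809 ± 88.05.

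Several groups were higher at 48 h. The NF-kB list had a median of 1.23 (camera adjusted p = 1.74e-06, adjusted p = 0.122 with an estimated correlation). The filter on low values raises this median. Among the 15 members with a control mean of at least 10 at the other time it was 0.78, with 13 higher and 1 lower (camera adjusted p = 1.99e-06). Mesenchymal genes rose in 13 of 18 and fell in 3 (median 1.37, camera adjusted p = 3.56e-06, adjusted p = 0.122 with an estimated correlation). The intermediate filament gene VIM fell from 4634 ± 261 to 3657 ± 153. Fibroblast markers moved with this group: 4 of 4 tested were higher, COL3A1 going from 166 ± 14.2 to 259.8 ± 3.27. Only 2 fibroblast markers had a control mean of at least 10 at the other time, and those 2 were higher. Neuronal genes rose in 16 of 20 and fell in 1 (median 1.73, camera adjusted p = 1.29e-06, adjusted p = 0.122 with an estimated correlation). The filter raises these values too, and among the 17 members with a control mean of at least 10 at the other time 13 rose and 1 fell (median 0.89, camera adjusted p = 1.99e-06). Genes reported as responding to HDAC inhibitors rose in 7 of 11 and fell in 3 (median 0.83, camera adjusted p = 0.00699, adjusted p = 0.122 with an estimated correlation). The chaperone HSPA2 rose from 429 ± 18.9 to 1629.8 ± 27.6, and CDKN1A from 387 ± 80.1 to 757 ± 107. Of 25 p53 targets 12 rose and 4 fell (median 0.20, camera adjusted p = 0.0324, 0.0563 without control replicate 3, adjusted p = 0.41 with an estimated correlation). BAX, a pore-forming pro-apoptotic protein, rose from 349.9 ± 21.5 to 571 ± 43.8. Interferon-stimulated genes rose in 12 of 21 and fell in 4 (camera adjusted p = 0.0314, adjusted p = 0.229 with an estimated correlation). The antiviral gene IFIT1 rose from 9.22 ± 0.704 to 91.8 ± 12.9. Antigen presentation genes rose in 10 of 16 and fell in 3 (camera adjusted p = 0.0421, adjusted p = 0.466 with an estimated correlation). Without control replicate 3 or SAHA replicates 1, 2 or 3, the interferon list stood at 0.0522, 0.251, 0.213 and 0.242 and the antigen presentation list at 0.0538, 0.153, 0.097 and 0.181. Without a SAHA library, members silent in controls could not pass the filter on low values, so those values also rest on a changed set of members. With only genes of a control mean of at least 10 at the other time, the interferon and antigen presentation lists stood at 0.129 and 0.184. Adjusted over the list alone, counts were the same for the other lists described so far at 48 h.

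Of the 11 deacetylases, 4 rose and 3 fell at 48 h (camera adjusted p = 0.952). HDAC1 fell from 860.1 ± 35.7 to 650.1 ± 59.3 (log2 change -0.41, limma adjusted p = 4.13e-05) and HDAC6 from 522 ± 7.25 to 357 ± 10.997 (log2 change -0.55, adjusted p = 1.06e-06). HDAC11 fell from 89.4 ± 6.81 to 43.97 ± 9.96 (log2 change -1.03, limma adjusted p = 3.35e-05), while HDAC9 rose from 64.7 ± 0.677 to 107 ± 7.82 (log2 change 0.72, adjusted p = 0.00016). HDAC7 was at 465 ± 78.5 in controls and 569 ± 45.5 with SAHA (limma adjusted p = 0.00845, 0.0693 and 0.0503 without control replicate 3 or SAHA replicate 1, and 0.107 without the mean-variance trend). HDAC8 was at 202 ± 28.2 and 249 ± 12.6 (limma adjusted p = 0.0151, 0.0916, 0.0616 and 0.0574 without control replicate 2 or 3 or SAHA replicate 1, 0.0614 without the trend, and 0.0554 in the authors' table). HDAC2 was at 925 ± 30.6 in controls and 1046 ± 67.7 with SAHA (limma adjusted p = 0.0239, 0.0652, 0.0504, 0.12 and 0.0828 without control replicate 1 or 2 or SAHA replicate 2 or 3, and 0.1 without the trend). HDAC3, at 259 ± 6.03 and 260.5 ± 21.7, did not pass (adjusted p = 0.971), nor did HDAC5, at 298 ± 16.3 and 269.9 ± 19.4 (adjusted p = 0.17). MYC fell from 3032 ± 60.03 to 1283 ± 31.4 (limma adjusted p = 1.05e-14). CCND1 was at 2298 ± 126.2 and 1943 ± 209 (log2 change -0.25, limma adjusted p = 0.00366, and 0.0805 without the mean-variance trend).

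Limma called 9116 of 15383 tested genes at 48 h, with 4295 higher and 4821 lower at a Benjamini-Hochberg adjusted p under 0.05. With equal totals the balance turned to 4726 higher and 4261 lower, and edgeR called 4612 higher and 4468 lower. At least 2-fold changes numbered 2582, with 1737 upward and 845 downward. The count at least 2-fold higher was 1038 to 1113 without any 1 SAHA library, for the same reason as at 24 h, and 1686 to 1768 with the tested genes of all 6 libraries. No list kept its call with an estimated correlation. The cohesin (0.00427) and HDAC-inhibitor (-0.0651) lists lost it with estimates below the preset 0.01, although most estimates were higher. At least 2-fold changes numbered 4440 without the filter and 1339 with a minimum of 50.

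The third comparison asked whether the effect of SAHA differed between the times, by the interaction of treatment and time over 12 libraries. Some genes that SAHA lowered at 24 h were at or above control at 48 h. The metalloproteinase MMP24 fell from 521 ± 60.03 to 53.8 ± 10.3 at 24 h and stood at 395 ± 48.2 in controls and 449 ± 26.2 with SAHA at 48 h. The tight junction gene CLDN2 fell from 1542 ± 72.4 to 276 ± 70.3 and then rose from 2417 ± 97.6 to 4228 ± 884, and PLAU, the urokinase plasminogen activator, fell from 192 ± 31.6 to 58.4 ± 15.1 and then rose from 158 ± 13.6 to 374 ± 35.6. CYP4F2, a fatty acid hydroxylase, rose from 15.9 ± 2.08 to 1285 ± 124.6 at 24 h and less, from 21.04 ± 9.12 to 41.3 ± 8.39, at 48 h, where it was still called (limma adjusted p = 0.00323).

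The remaining genes with the most positive differences were CPLX2, at 14386 ± 441 and 13315 ± 1521 at 48 h, and NOX1, a superoxide-producing oxidase, which went from 137 ± 9.15 to 10.9 ± 6.32 at 24 h and from 246 ± 32.4 to 132 ± 9.85 at 48 h. Of the most negative, GPR50 stood at 8.99 ± 2.27 with SAHA at 48 h, and the serine protease TMPRSS9 went from at least 201-fold above its controls at 24 h (173 ± 31.96) to 4.13 ± 2.65. ACSBG1, an acyl-CoA synthetase, stood at 247 ± 22.7 and 2.44 ± 1.25 with SAHA at 24 h and 48 h. DNAH3, another ciliary dynein chain, rose from 7.52 ± 1.63 to 544 ± 37.4 at 24 h and was at 12.7 ± 1.04 and 22.9 ± 1.15 at 48 h (limma adjusted p = 0.014, 0.055 without SAHA replicate 3, and 0.0601 in DESeq2). The differences of these 10 genes had limma adjusted p from 7.95e-13 for CPLX2 to 5.45e-06 for NOX1. For CDKN1A the difference of -0.33 did not pass (limma adjusted p = 0.171, and 0.00481 with replicate as a block), nor did that of 0.20 for HDAC2 (adjusted p = 0.0752, and 0.0389 with replicate as a block). The HDAC2 difference was also called by limma with TMM scaling (adjusted p = 0.0177) or equal totals (0.0123), and by edgeR (0.038).

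By list, the fall of DNA replication genes was smaller at 48 h in 34 of 36 genes, with 1 negative (median difference 1.22, camera adjusted p = 2.83e-17, adjusted p = 0.0476 with an estimated correlation). Differences were also positive for 15 of 17 recombination and Fanconi genes (median 1.12, camera adjusted p = 3.99e-08, adjusted p = 0.0593 with an estimated correlation). They were positive for all 18 core histone genes (median 1.40, camera adjusted p = 2.68e-09, adjusted p = 0.0764 with an estimated correlation) and 9 of 14 G1 genes (median 0.59, camera adjusted p = 0.00345, adjusted p = 0.109 with an estimated correlation). The mitosis list went the other way, with 18 of 34 genes negative and 7 positive (median -0.40, camera adjusted p = 0.0196, 0.0518 without control replicate 1 and 0.0853 without SAHA replicate 2 at 48 h, adjusted p = 0.763 with an estimated correlation). Both tables hold the same normalised values for all 12 libraries, so control levels can be set side by side. All 36 replication genes and all 34 mitosis genes were lower in each of the 3 controls at 48 h than in each at 24 h, where chance gives 5.00% and 20.95% of 14594 expressed genes were. The median log2 changes were -1.08 and -1.17. TYMS in controls stood at 806 ± 29.3 at 24 h and 341 ± 26.8 at 48 h, and MKI67 at 7284 ± 234 and 2683 ± 145.

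Cholesterol genes differed in 18 of 23, all negative (median -1.10, camera adjusted p = 1.96e-10, adjusted p = 0.0764 with an estimated correlation). At 24 h that list had 7 genes higher, led by the sterol reductase TM7SF2 (from 100.5 ± 9.03 to 379 ± 57.1), and 7 lower. NF-kB targets differed upward in 11 of 18 and downward in 2 (median 0.76, camera adjusted p = 0.00435, adjusted p = 0.483 with an estimated correlation). The chemokine CXCL5 fell from 3199 ± 187 to 839 ± 115.8 at 24 h and stood at 5220.2 ± 480.1 and 5332 ± 128.5 at 48 h. Chaperone genes differed upward in 9 of 14 and downward in 1 (median 0.39, camera adjusted p = 0.00857, adjusted p = 0.385 with an estimated correlation). Ribosome biogenesis genes differed upward in 11 of 23 and downward in 1 (median 0.26, camera adjusted p = 0.00268, adjusted p = 0.413 with an estimated correlation). Lysosome and autophagy genes differed downward in 10 of 22 and upward in 2 (median -0.31, camera adjusted p = 0.0135, adjusted p = 0.609 with an estimated correlation). NPC1, the cholesterol exporter of lysosomes, went from 573 ± 31.7 to 2567 ± 109.7 at 24 h and from 504 ± 16.5 to 415 ± 5.01 at 48 h. Neuronal genes differed downward in 15 of 26 and upward in 3 (median -0.95, camera adjusted p = 0.0112, 0.131, 0.0997 and 0.096 without SAHA replicate 1, 2 or 3 at 24 h, 0.166 with only genes of a mean of at least 10 over the 6 controls, adjusted p = 0.116 with an estimated correlation). Without a SAHA library of 24 h, neuronal genes silent in controls and low at 48 h could not pass the filter, so those values also rest on a changed set. Adjusted over the list alone, the differing genes numbered 19 for cholesterol, 13 downward and 3 upward for lysosome, 17 and 4 for neuronal, 1 and 10 for G1 and 18 and 8 for mitosis genes.

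Over all genes, limma called a difference for 7464 of 16312 tested genes, with 3711 positive and 3753 negative at a Benjamini-Hochberg adjusted p under 0.05. This even balance depended on the scaling, with 4378 positive and 3262 negative by TMM and 4494 and 3177 with equal totals. With an estimated correlation, DNA replication was the 1 list of 11 that kept its call.

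**Figure D2:**
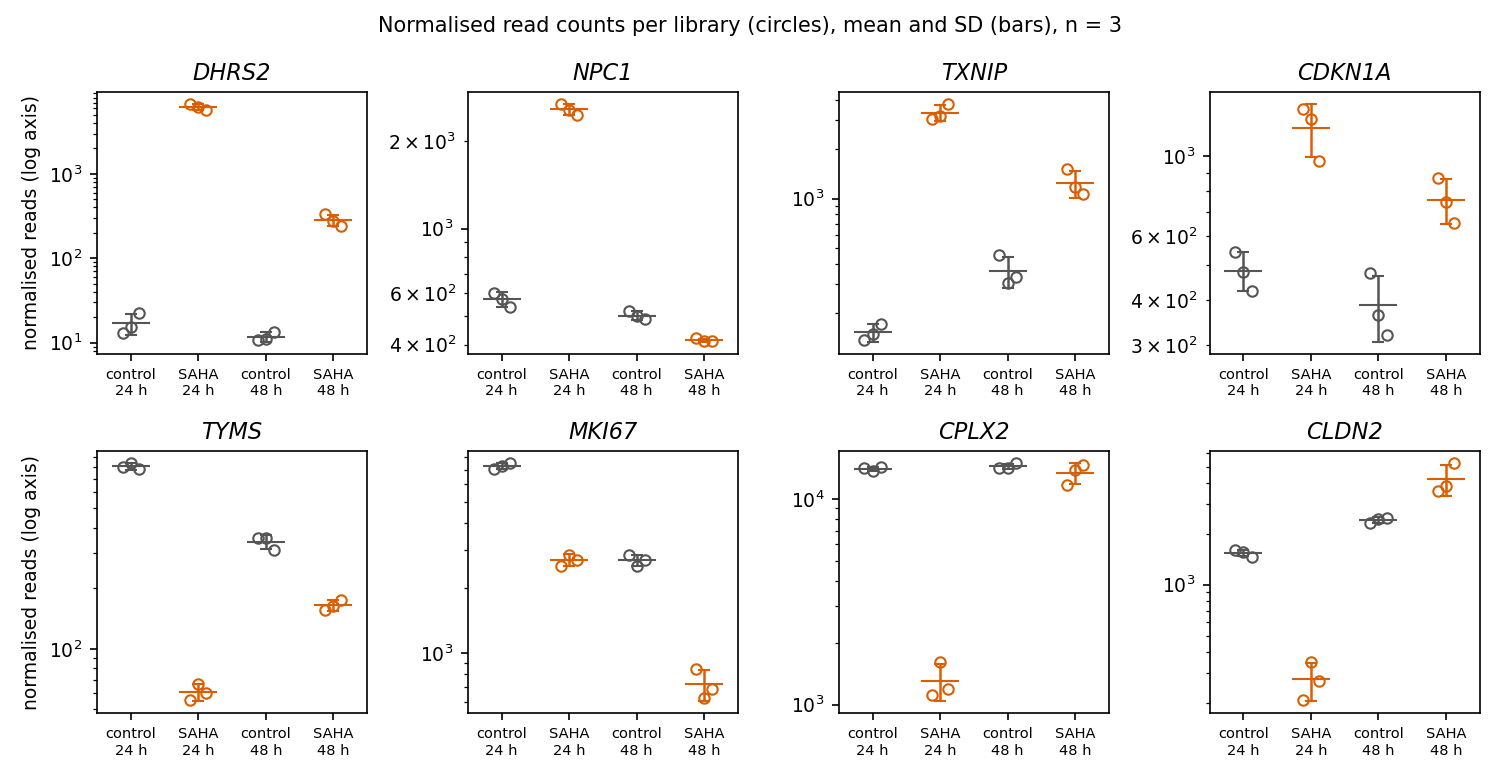
Normalised reads (vertical log axis) of selected genes in the 4 groups, with 1 point per library and a bar at the mean of 3 libraries. TYMS goes from 806 ± 29.3 to 60.8 ± 5.69 at 24 h and from 341 ± 26.8 to 165 ± 9.79 at 48 h.

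The overlap of calls asked how far both times shared their direction. Of 14947 genes tested at both times, 2829 were higher at both (1355 for independent lists) and 3252 lower at both (1764 for independent lists), and 865 were called in opposite directions. The 489 that were higher and then lower include NPC1 and INSIG1, and the 376 that were lower and then higher include CLDN2, PLAU and BAX. Across genes, which are not independent replicates, the log2 changes at both times had a Pearson correlation of 0.771 and a Spearman correlation of 0.659. Among genes called in one direction at both times, 72.8% had the smaller change at 48 h, with a median ratio of the 48 h to the 24 h change of 0.717. The controls of both times were separate libraries.

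Direction varied with the level in controls. Genes were ranked by their control level at the other time, so that chance error in the controls could not make low genes rise. In the lowest of 10 bins, 84.6% of genes were higher at 24 h and 2.46% lower, and in the highest bin 27.3% were higher and 52.5% lower. At 48 h 65.1% of the lowest bin was higher. The filter on low values keeps a gene silent in controls only if it rose, so the ranking was repeated on genes with a control mean of at least 10, an alternative chosen after seeing the data. In the lowest of 5 bins of these, 38.5% (exact 95% binomial interval 36.7 to 40.3) were higher at 24 h and 18.2% (16.8 to 19.7) lower, and in the highest bin 27.96% were higher and 50.1% lower. At 48 h the lowest bin had 36.5% higher and 13.1% lower, and the highest 19.3% and 50.5%. CCND2, GPR50 and CEACAM20, without a read in controls at 24 h, belong to the silent genes, and MYC and CCND1, both lowered at 24 h, to the abundant ones.

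**Figure D3:**
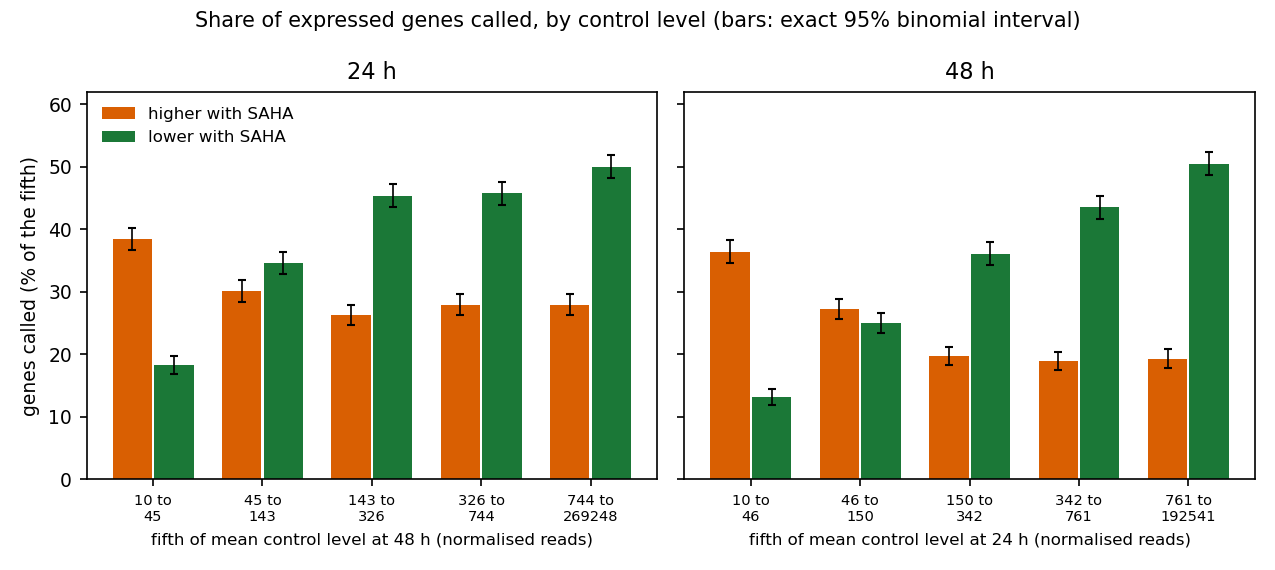
Percent of genes called higher and lower (vertical axis) in each of 5 bins of control level (horizontal axis, lowest to highest) at 24 h and 48 h, among genes with a control mean of at least 10 at the other time, with exact 95% binomial intervals. The share called lower goes from 18.2% in the lowest bin to 50.1% in the highest at 24 h.

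The authors' deposited table of DESeq2 results gave 6563 genes higher and 5416 lower at 24 h among 24515 with an adjusted p, and 4320 higher and 4129 lower at 48 h among 22058. Limma called 99.5% of those it also tested in the same direction at 24 h and 99.9% at 48 h, and none in the opposite one.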

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

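Of the tests in this part, those of the other nuclear RNAs, of dilution by unaffected cells and of draws that keep the replicate pairs were chosen only after the result was seen, as were the bins of genes with a control level of at least 10. Each gene difference given next is the log2 effect of SAHA at 48 h minus that at 24 h and passed limma's interaction test at a Benjamini-Hochberg adjusted p under 0.05, as did 7464 genes in all. In 1 of 100 drawn assignments of the 12 libraries to 4 groups, the real one, the count was this large, and the highest other was 6745. The share was thus under 0.05, the limit set beforehand. Such free draws also mix SAHA with control libraries, so they test whether the groups differ at all. They cannot exclude chance for the difference between times alone. Of 100 assignments drawn from the 320 that keep the replicate pairs, 5 gave a count as large, the real one included, and the highest other was 8768. In the 4 others the contrast became that of SAHA against control over both times, a structure of the samples, and the highest of the remaining 95 was 172. With the pairs kept, the share was therefore not under 0.05.

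Rises that were smaller or gone at 48 h gave the most negative differences: -6.51 for GPR50, -5.51 for TMPRSS9, -5.35 for ACSBG1, -5.25 for CYP4F2, -5.21 for DNAH3, -4.91 for CEACAM20, -4.76 for SYN1, -4.31 for DNAH12, -4.30 for CEACAM22P, -4.16 for ATP1B2, -3.99 for DHRS2 and -3.82 for ALDOC. Next came -2.95 for NGFR, -2.67 for TXNIP, -2.45 for TEX15, -2.05 for NRXN2, -1.94 for EGR2, -1.73 for TM7SF2, -1.61 for HDAC5, -1.54 for NCAM1 and -1.40 for CCN2. Smaller negative differences were -1.22 for SRXN1, -1.16 for MEG3, -1.11 for BIRC3, -1.02 for TP53INP1, -0.84 for HDAC3, -0.83 for GSN, -0.79 for MT1X, -0.72 for BMF and -0.49 for CLU. Genes that fell further, or fell only in the 48 h test, included -3.69 for INSIG1, -2.44 for NPC1, -2.17 for ACSL3, -2.14 for RBP4, -1.81 for MYO7B, -1.66 for HABP2, -0.97 for SLC23A1, -0.71 for MYC, -0.48 for HDAC1, -0.81 for HDAC11, -0.47 for MKI67 and -0.39 for HDAC6, INSIG1, NPC1 and ACSL3 having risen at 24 h. HDAC11 stood at an adjusted p of 0.0594 and 0.0581 without control replicate 3 at 24 h or SAHA replicate 1 at 48 h. Falls that were smaller, gone or turned at 48 h gave positive differences: 3.45 for MMP24, 3.32 for CPLX2, 3.30 for CLDN2, 2.95 for PLAU, 2.80 for NOX1, 2.74 for MACROH2A2, 2.67 for TYMS, 2.65 for IFIT3, 2.48 for H2AC21, 2.48 for BAAT and 2.25 for ALDH3A1. Others were 2.17 for H2AC4, 2.10 for COL5A2, 2.06 for E2F1, 2.04 for CACNG6, 1.99 for GALNTL6, 1.97 for CXCL5, 1.96 for UTP20, 1.85 for PSMB8, 1.74 for BID, 1.55 for HDAC7 and 1.44 for LMNB1. The rest of the positive differences were 1.32 for COL3A1, 1.25 for TP53I3, 1.22 for CCND1, 1.15 for HSPH1, 1.14 for CTPS1, 1.08 for BAX, 1.01 for XBP1, 0.99 for VIM, 0.67 for HDAC4, 0.62 for HDAC8 and 0.56 for FOXA1. Of these differences, the call ended in edgeR for NGFR (adjusted p = 0.069), NCAM1 (0.11, and 0.103 in DESeq2), NRXN2 (0.0552) and CEACAM20 (1), and without the variance trend for HABP2 (0.0647), with the cause not tested. TMEM255A (2.10) and HSPA2 (1.07) rose more at 48 h than at 24 h. Among lists, median differences were 1.40 for core histones, 1.22 for DNA replication, 1.12 for recombination and Fanconi repair, 0.76 for NF-kB targets, 0.59 for G1 genes, 0.39 for chaperones, 0.26 for ribosome biogenesis, -0.31 for lysosome genes, -0.40 for mitosis, -0.95 for neuronal genes and -1.10 for cholesterol genes, and of these DNA replication alone kept its call with an estimated correlation.

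MALAT1, a nuclear-retained RNA, took 2.13% ± 0.26 of reads in controls and 8.34% ± 1.04 with SAHA at 24 h (n = 3 each), and 2.93% ± 0.37 and 5.54% ± 0.72 at 48 h, a difference of effects of -1.14. Loss of cytoplasmic RNA would raise nuclear RNAs alike. At 24 h MALAT1 changed by 2.02 on the log2 scale, the other long nuclear RNAs NEAT1 and MEG3 by 1.32 and 2.28, and the small RN7SK, RMRP and RPPH1 by 0.19, 0.15 and 0.12. The median of these 5 was 0.19 with an interquartile range of 1.17, so the test by their median could not decide. The small RNAs (SE 0.09, 0.15 and 0.19) were not called, which argues against a rise of all nuclear RNAs alike. For the long nuclear RNAs this explanation stays open at 24 h. At 48 h MALAT1 changed by 0.87 and MEG3 by 1.12, whereas NEAT1 did not pass (-0.11, limma adjusted p = 0.511), so these long RNAs were not all called higher then. The effect on NEAT1 at 48 h minus that at 24 h was -1.43. A share of a library's reads does not depend on the authors' scaling. MALAT1's log2 change of 2.06 (SE 0.14), after rescaling to equal totals without it, follows from these shares and is no separate test. A response of MALAT1 itself to SAHA also stays open.

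Changes were smaller at 48 h, with 4798 genes changed at least 2-fold at 24 h and 2582 at 48 h. Lower depth is argued against, since with all libraries thinned to 7321966 reads the ratio of these counts was 1.88. Dilution by unaffected cells alone, with affected cells unchanged since 24 h, would leave 1 common share of each rise at 48 h. For this, 87 genes were taken that rose at 24 h from under 10 to a SAHA mean of at least 100. Of these, 70.1% kept a share more than 3 standard errors from the median of 14.2% (33 above and 28 below). The unequal shares argue against dilution as the only cause, and dilution beside a changing response stays open. A change of the response over time, or loss of drug activity, may account for the pattern and was not tested. The controls also changed between times. Of 14594 expressed genes, 20.95% were lower in each 48 h control than in each 24 h control, all 36 replication genes among them, and 20.92% were higher. How far this sets the smaller changes at 48 h was not tested.

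Genes low in controls rose more often than they fell at 24 h. Genomic DNA in the SAHA libraries would raise silent genes alike. However, the 389 olfactory receptor genes together had 274 reads with SAHA and 325 in controls, a normalised ratio of 1.02 (exact 95% interval 0.868 to 1.21). The pooled reads of 27272 other genes with a level under 1 in 48 h controls had a ratio of 7.44 (7.31 to 7.58). Genes with many reads weigh most in a pooled ratio, so 7.44 is not the rise of a typical gene. Selection by the filter on low values is argued against as the whole cause by the lowest of 5 bins of genes with a control level of at least 10, where 38.5% were higher and 18.2% lower. The filter does set part of the 84.6% in the lowest bin. Expression of genes silent in controls, such as CCND2, after HDAC inhibition may thus be biological, as a hypothesis.

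The 6 libraries of a time split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 11233 genes at 24 h (4798 at least 2-fold) and 9116 at 48 h (2582), and the highest of the other splits 0 for each by limma, with at most 154 and 168 genes at an unadjusted p under 0.05. This held for the 4 splits that, with the real one counted, part 3 replicate pairs as well as for the 6 that part 1. Each other split puts 2 libraries of one condition against 1, so each of its groups holds SAHA and control libraries. The effect of SAHA then widens the spread within groups and holds gene calls down. These low gene counts therefore do not measure what chance alone would give. For gene lists the real split gave 13 calls at 24 h, 3 of the 10 splits gave as many, and the highest other gave 14, or 11 among splits parting 3 pairs. At 48 h 1 split, the real one with 18, was that high, and the highest other gave 15. Because each other split sets 2 libraries of one condition against 1, part of the SAHA effect stays in its contrast. List calls in those splits may come from that part. The list counts therefore do not measure what chance alone would give either.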

How the results depend on the processing

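All alternatives were planned except 4, chosen after seeing the data: bins of genes with a control mean of at least 10, bins by the mean over 12 libraries, leaving out a library with the tested genes kept, and lists on genes chosen on controls alone (a control mean of at least 10 at the other time, or over all 6 controls for the difference). No called direction of the 98 named genes or of the lists reversed under any alternative run, but the balance of higher and lower calls over all genes turned, at 24 h by TMM (5215 higher and 6075 lower) and at 48 h with equal totals (4726 and 4261), among others. Calls at 24 h numbered 9301 to 10589 without any 1 library, at 48 h 7720 to 8671, and for the difference 6703 to 7303. At least 2-fold changes numbered 3596 to 4660 and 1911 to 2502, and lists past the threshold 13 to 15, 15 to 19 and 10 to 11. At least 2-fold changes were 7767 at 24 h and 4440 at 48 h without the filter, and 2966 and 1339 with a minimum of 50, since more or fewer genes were tested.

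With replicate block the calls numbered 12022 at 24 h, 9351 at 48 h and 8273 for the difference. It changed no call of a named gene or list beyond HDAC6 at 24 h, the differences of CDKN1A and HDAC2, and the replacement histone list at 48 h. With an estimated correlation camera called 0 lists at 24 h and 0 at 48 h (7 and 12 at an unadjusted p under 0.05) and 1 for the difference, against 13, 18 and 11 with the preset one. Fry called 25, 26 and 22, and camera on genes chosen on controls alone 14, 16 and 10. Mitosis for the difference ended at 0.0519 in fry, and antigen presentation at 48 h at 0.0528 with equal totals. The overlap of calls in one direction at both times was 6081, and 1757 for at least 2-fold changes, a narrower set by construction.

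The share of the lowest bin that was higher at 24 h, 84.6%, was 89.5% with control levels of the same time, 80.8% for at least 2-fold changes, 82.3% with equal totals, 38.5% among genes with a control mean of at least 10 and 59.5% in bins by the mean over 12 libraries. At 48 h 65.1% became 67.8%, 58.6%, 36.5% and 39.6% in the same order without equal totals. In the last bins the genes differ by construction. Scaling by TMM or equal totals moved the median log2 change of all genes by -0.06 at 24 h, 0.05 at 48 h and 0.09 for the difference at most. Simulated 1.5-fold changes were recovered in 71.6% at 24 h, 82.1% at 48 h and 52.2% for the difference. The simulation changed far fewer genes than were called in the data.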

Other observations

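Of the tests in this part, only the counts among members with a control mean of at least 10 were chosen after seeing the data. INSIG1, ACSL3 and COL5A2 were named after their values were seen. Metallothioneins, which bind zinc and copper, were higher in 3 of 3 tested members at 24 h and 3 of 4 at 48 h: MT1X rose from 139.7 ± 9.60 to 503 ± 56.6 at 24 h, MT1F from 27.1 ± 4.54 to 61.1 ± 7.58 and MT2A from 464 ± 44.9 to 974 ± 139.7, although reads of these similar copies are hard to assign. Glycolysis genes split, with 7 of 19 higher and 8 lower at 24 h, or 8 and 8 adjusted over the list alone (camera adjusted p = 0.835, median -0.11, mean 0.14). ALDOC, the brain form of aldolase, rose from 44.5 ± 5.00 to 746 ± 53.96 at 24 h and stood at 66.5 ± 17.2 and 76.5 ± 12.04 at 48 h, whereas the glucose transporter SLC2A1 fell from 1424 ± 128.4 to 532 ± 34.3 and from 1125 ± 46.003 to 436 ± 91.6. Immediate-early genes did not pass as a list (camera adjusted p = 0.564), but EGR2, a growth-factor-induced transcription factor, rose from 98.3 ± 13.7 to 1635 ± 192 at 24 h and from 129 ± 7.69 to 559.9 ± 76.6 at 48 h. Mesenchymal genes did not pass at 24 h (9 higher and 2 lower of 19, camera adjusted p = 0.106), although CCN2 rose from 1186 ± 96.3 to 12907 ± 1201 and VIM fell from 5585 ± 337 to 2218 ± 181. Fibroblast markers then had 3 higher and 1 lower of 4, with COL3A1 falling from 178 ± 5.80 to 112 ± 19.1. Of the 2 markers with a control mean of at least 10 at 48 h, 1 was higher and 1 lower.

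At 24 h 8 of 21 interferon-stimulated genes were higher and 5 lower, 10 and 3 of 16 antigen presentation genes and 9 and 7 of 18 NF-kB targets. The filter on low values admits members silent in controls only if they rose, which raises the counts of higher genes. Among members with a control mean of at least 10 at 48 h, 4 of 17 interferon genes were higher and 5 lower. Antigen presentation then had 8 and 3 of 14, and NF-kB targets 5 and 7 of 14 (median -0.33, against 0.38 for the 18). IFIT1 rose from 15.1 ± 1.41 to 189.7 ± 8.08, while IFIT3, of the same interferon-induced family, fell from 22.9 ± 7.53 to 5.36 ± 1.49 at 24 h and rose from 28.3 ± 3.20 to 48.9 ± 8.76 at 48 h. HLA-DPB1, an MHC class II chain with similar relatives, had no read in controls and reached 31.2 ± 9.63 (at least 36.4-fold higher), and the immunoproteasome gene PSMB8 fell from 81.6 ± 4.91 to 25.9 ± 2.85. IL1A rose 46.5-fold (95% counting interval 14.8 to 219). The interferon, antigen presentation and NF-kB lists did not pass at 24 h (camera adjusted p = 0.435, 0.0992 and 0.582). Of 9 alveolar and airway markers 6 fell and 3 rose (camera adjusted p = 0.196). The airway and liver regulator FOXA1 fell from 695 ± 27.5 to 186 ± 14.3, and LAMP3, a lysosomal protein of type II alveolar cells, rose from 3.19 ± 0.956 to 39.5 ± 11.2. Of 6 cancer-testis genes 3 rose and 1 fell (camera adjusted p = 0.537), TEX15, a germ cell gene, rising from 16.1 ± 3.98 to 172 ± 18.99. Among the 3 cancer-testis genes with a control mean of at least 10 at 48 h, 1 rose and 1 fell (median -0.15, against 0.66 for the 6). The p53 targets TP53INP1 and TP53I3 went apart, the first rising from 213 ± 11.1 to 669 ± 20.2 and the other falling from 371 ± 14.1 to 101 ± 12.2. The chaperones HSPH1 and HSPA2 did so too, at from 1544 ± 72.2 to 766 ± 247 and from 535 ± 46.6 to 964 ± 59.9. CLU, a secreted chaperone, rose from 5733 ± 551 to 14313 ± 1363, and GSN, an actin-severing protein, from 720.4 ± 71.1 to 1340.1 ± 179. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose from 596 ± 29.6 to 1621 ± 194 at 24 h and fell from 669 ± 62.3 to 139 ± 7.57 at 48 h. ACSL3, which activates fatty acids, went from 4228 ± 138 to 9863 ± 183 and from 5179.8 ± 142 to 2689 ± 40.7, and the collagen gene COL5A2 from 6520.2 ± 257 to 3061 ± 138 and from 6248 ± 211 to 12599 ± 578.

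As a hypothesis, genes next to each other on the genome could respond together to a drug that acts on chromatin. Across 5244 pairs of adjacent tested genes on opposite strands that do not overlap, the Pearson correlation of log2 changes at 24 h was 0.0415, within the range of 1000 random gene orders (-0.0429 to 0.0439, SD 0.0138), of which 1 was as high. The test set beforehand asked for a value above every order. It missed that by less than the SD, so the data at 24 h leave the hypothesis open. Of pairs with both genes called, 51.2% went in one direction, where 50.1% is expected from the shares of calls. At 48 h the correlation over 5124 pairs was 0.0872, above the highest of 1000 random orders (0.0459), and 56.9% of pairs went in one direction against 50.6% expected. The 48 h value goes with the hypothesis, although the test was set for 24 h, and genes are not independent replicates. Pairs had no limit of distance, and the random orders did not keep the control levels of neighbours, with which direction varied. Other reasons for such a correlation were not tested. Both correlations are small.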
